A study of Homo sapiens with 8 samples.

How the data were processed

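Small RNA was profiled in SW-620 cells, an established human colorectal cancer line, on a single slide of Agilent human miRNA arrays. The 8 arrays were hybridised with Cy3-labelled total RNA from 3 vehicle controls, 3 samples treated with 10 µM menadione and 2 treated with 10 µM plumbagin, all collected after 24 h. Per the labels, RNA was extracted with Trizol, dephosphorylated and ligated to Cy3-pCp. The labels number the replicates but do not say that they were separate cultures, so every p-value measures only the spread between these samples.

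Per the file headers, the authors extracted spot intensity with Agilent Feature Extraction 11.5.1.1 on a grid of genome build hg19, with additive spatial detrending and no multiplicative detrending. The deposited scanner files hold background-subtracted intensity for each spot, the mean spot and median local background intensity, a summed intensity per miRNA, and detection and outlier flags, with no scaling between arrays. The deposited series table holds log2 values for each miRNA. Between 99.7% and 99.9% of its values per array lay within 0.001 of the log2 summed intensity minus a constant for that array, and those values were used only as an alternative.

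One value per miRNA and array was computed from the background-subtracted intensity of the 50980 spots of human miRNA probes, which represent 5893 probes and 2549 miRNAs. Spots flagged as non-uniform or as population outliers were left out and the other spots of a probe were averaged. Each array was divided by the 75th percentile of its signal over the 285 probes detected on all 8 arrays. Values below a floor of 0.107 on the scaled intensity (-3.22 on the log2 scale) were set to it. The floor was the highest, over the arrays, of the 1st percentile of the scaled signals of the probes detected on that array. Each miRNA was represented by its probe with the highest mean log2 value. The 350 miRNAs detected on all arrays of at least 1 group were tested, of which 128 lay at the floor on all 8 arrays and 140 on none.

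All 8 arrays were fitted together in limma 3.58.1 under R 4.3.3 (files were read with data.table version 1.17.8), using lmFit and eBayes with an intensity trend and group as the only term. The prior degrees of freedom were 0.677 beside 5 residual degrees of freedom. In a fit of only the 140 miRNAs never at the floor, added after the data were seen, the prior degrees of freedom were 20.7. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 350 miRNAs with a threshold of 0.05, and intervals are 95% limma intervals. The comparisons were each compound against vehicle and plumbagin against menadione. Measures with 1 value per array were compared with exact permutation tests, for which the smallest p that 3 against 3 arrays allow is 0.1, as is that of 3 against 2. A correlation between the responses to the compounds was set against 1000 simulated data sets with unchanged groups that share their controls. The 3 controls could not be divided between the compounds.

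Lists of miRNAs were fixed before the data were examined and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They covered p53-responsive miRNAs, miRNAs targeting NRF2 or KEAP1, hypoxia-responsive miRNAs, the miR-17-92 cluster with its paralogs, and the let-7, miR-200, miR-15/16, miR-29 and miR-30 families. Further lists were the miR-23/24/27 clusters, the cluster of miR-221 and miR-222, miRNAs raised or lowered in colorectal tumours, intestinal epithelial miRNAs, and miRNAs of blood, of fibroblast and smooth muscle, and of endothelium, muscle, liver and neuron. The last lists held array entries overlapping tRNA, snRNA or other abundant small RNA, and GC-rich entries that are bright on this array type, as a sign of RNA quality. Of 190 names, 185 were on the array, and the 16 lists with at least 3 tested members were tested. Some miRNAs belong to more than 1 list. The set tests were repeated with camera's estimated correlation and with fry, whose directional test asks whether the members move, on balance, one way and whose mixed test asks whether they change in either direction.

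The rule for named miRNAs took those past the threshold with non-overlapping arrays. Where fewer than 5 passed, it took the 10 miRNAs with the smallest unadjusted p for each compound and the 6 smallest for plumbagin against menadione, and up to 4 members of each list. Of these list members the text names the first 2 of each list called in that comparison. Positions are those of the probes in the array's annotation on hg19.

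The alternatives fixed before the data were examined changed the scaling (percentile over all probes, quantile normalization, none, median), the background correction (normexp with an offset of 50), the signal column, the source (the deposited series table), the averaging of probes, the floor, the outlier spots, the filter, the variance model, array weights, the arrays in the fit, a block for replicate number, a block for the column of the slide, and each array left out in turn. Alternatives added after the data were seen left out miRNAs at the floor on any array, set the floor from 3 SD of the negative-control spots, or regressed probe GC content out of each array, also without control replicate 3 or menadione replicate 1. Fits were tested on simulated data with changes of known size. The number of arrays limits the precision of every value, and the controls on the arrays served only as measures of array quality.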

Results

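The study profiled miRNAs in SW-620 colorectal cancer cells after 24 h of vehicle, menadione or plumbagin, each compound at 10 µM. Menadione is the synthetic naphthoquinone known as a vitamin K precursor, and plumbagin is a plant naphthoquinone that carries an added hydroxyl group. There were 3 control arrays, 3 menadione arrays and 2 plumbagin arrays. Between 11.1% and 14.9% of the 2549 miRNAs on the array were detected per sample. Detected miRNAs numbered 371 ± 12.5 (SD, n = 3) in controls, 326 ± 43.0 (n = 3) with menadione and 323 ± 1.41 (n = 2) with plumbagin. Exact permutation tests against controls gave p = 0.2 for menadione and p = 0.1 for plumbagin, the smallest p this design allows. The 75th percentile of the signal was 376 ± 41.1 in controls, 291 ± 132 with menadione and 314 ± 28.6 with plumbagin, with exact permutation p = 0.5 and 0.2. Menadione replicate 1 was the dimmest array, at a percentile of 140 and with 282 detected miRNAs. Its total signal of 18519 intensity units compared with 37567 to 67298 on the other arrays. On every array the brightest entry was miR-7975, which took 44.1% to 51.7% of the total signal. The controls and menadione replicate 1 lay in 1 column of the slide, and the other 4 arrays lay in the second column.

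**Figure D1:**
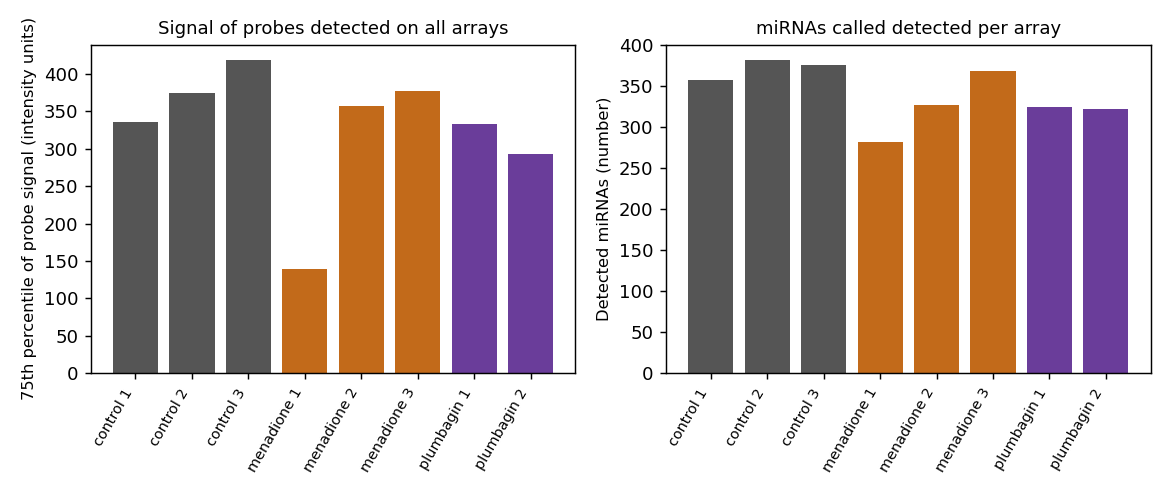
Signal and detection per array: the left axis gives the 75th percentile of the probe signal in intensity units and the right axis the number of detected miRNAs, with 1 bar per array coloured by group. Menadione replicate 1 had the lowest bar in each plot, at 140 intensity units and 282 miRNAs.

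The comparison of menadione with vehicle asks whether the compound changes the miRNA profile. No single miRNA passed the threshold in limma, and 5 lists did with camera at its preset correlation, of which 4 were lower and 1 was higher. With an estimated correlation 0 lists were called, and the smallest adjusted p was 0.353. miR-210-3p, the miRNA that hypoxia-inducible factors induce most directly, had a mean log2 scaled signal of -0.76 ± 0.20 (SD, n = 3) in controls and -1.70 ± 0.51 (n = 3) with menadione. Its log2 fold change of -0.94 (SE 0.27, a fold of 0.520) had a 95% interval from -1.61 to -0.28 and an adjusted p of 0.919. miR-100-5p, which targets the kinase mTOR, averaged -1.36 ± 0.22 in controls and -1.95 ± 0.20 with menadione, a log2 fold change of -0.59 (SE 0.16, adjusted p = 0.919). For each of these miRNAs, all 3 menadione arrays lay below all 3 control arrays. Under normexp background correction the log2 fold changes were -0.48 and -0.20, and without scaling between arrays -1.44 and -1.08.

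The smallest unadjusted p, 0.00340 in limma, belonged to miR-17-3p, an arm of the oncogenic miR-17-92 transcript, with a log2 fold change of -0.54 (SE 0.11, adjusted p = 0.919). It was detected on 2 of the 3 menadione arrays, and 2 arrays lay at the floor, so that its fold depends on the floor and went from 0 under normexp to -1.88 in the deposited series table. The log2 fold change was -0.51 (SE 0.14) for miR-130b-3p and -0.33 (SE 0.10) for miR-10a-5p, which is encoded in a HOX gene cluster. It was -0.42 (SE 0.14) for miR-331-3p and -0.36 (SE 0.13) for miR-140-3p, whose sign turned under normexp background correction (0.02). The signal of miR-324-5p lay at the floor on all 3 menadione arrays and averaged -2.54 ± 0.34 in controls, so that its fold depends on the floor. All of these miRNAs had lower signal on 3 of 3 menadione arrays than on any control array. On the hg19 build the probe of miR-210-3p lies on chromosome 11 from 568161 to 568175, that of miR-100-5p on chromosome 11 from 122022953 to 122022970, and that of miR-17-3p on chromosome 13 from 92002916 to 92002930.

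Among the lists, the miR-200 family, which maintains the epithelial state by repressing ZEB transcription factors, had 6 of 7 tested members lower and 1 at the floor on all arrays, with a mean log2 fold change of -0.30. Under other processing this mean went from -0.80 without scaling, where that of all miRNAs was -0.33, to -0.08 under normexp, where it was 0.01. Camera gave the family an adjusted p of 0.000684, and adjusted p = 0.353 with an estimated correlation. Its members miR-141-3p (-0.69, SE 0.21, at the floor on 2 arrays, with 0 under normexp and -2.21 in the series table) and miR-200c-3p (-0.31, SE 0.12, or -0.20 without menadione replicate 1) had an adjusted p of 0.919 and 1. All 5 tested p53-responsive miRNAs were lower, with a mean of -0.31. In the deposited series table their mean lay above the mean of all miRNAs (-0.18 against -0.27) but below the median (0.004). Their adjusted p was 0.00308, and adjusted p = 0.499 with an estimated correlation. They included miR-192-5p (-0.40, or -0.24 without menadione replicate 1) and miR-107 (-0.25, or -0.10 without it). Of 9 hypoxia-responsive miRNAs, 7 were lower and 1 was higher, with a mean of -0.25 and adjusted p = 0.00308, and adjusted p = 0.499 with an estimated correlation. All 5 members of the miR-23/24/27 clusters were lower with a mean of -0.25. In the deposited series table their mean lay above the mean of all miRNAs (-0.09 against -0.27) but below the median (0.004). Their adjusted p was 0.00576, and adjusted p = 0.499 with an estimated correlation. miR-24-3p (-0.29, or -0.11 without menadione replicate 1) and miR-23b-3p (-0.28, or -0.14 without it) were examples. Of 29 GC-rich entries that are bright on this array type, 23 were higher and 0 lower, with a mean of 0.17 that turned to -0.20 without scaling between arrays, where the median of all miRNAs moved by -0.30. Their adjusted p was 7.45e-05, and adjusted p = 0.499 with an estimated correlation. Examples were miR-7704 (0.45, SE 0.28, or 0.16 without menadione replicate 1) and miR-3196, for which all control arrays lay at the floor, so that its fold depends on the floor. Among all lists, members called over all miRNAs numbered 0, and 1 miRNA, miR-17-3p, was called when adjusted over the list alone.

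The size of these changes depended on the processing and on single arrays. Under 7 alternatives of scaling, background correction, signal column or source all 16 named miRNAs moved by over 1.5 times in at least 1. Leaving out scaling shifted miRNAs above the floor by a common amount. That alone moves small fold changes by over 1.5 times, so this count says little about single miRNAs. The list means ranged from -0.79 to -0.18 for p53 and from -0.69 to -0.15 for hypoxia. They ranged from -0.75 to -0.09 for miR-23/24/27 and from -0.20 to 0.24 for the GC-rich entries. The lowest value of each list came without scaling, where the mean of all miRNAs was -0.33. Without menadione replicate 1 the mean was -0.13 for p53, -0.08 for hypoxia, -0.08 for miR-23/24/27 and 0.00 for the GC-rich entries, of which 12 were then higher and 12 lower, and without menadione replicate 2 that of the GC-rich entries was 0.28. Without control replicate 3 it was -0.19 for p53, -0.16 for hypoxia and -0.15 for miR-23/24/27. With GC content regressed out, chosen after the data were seen, 0 of the 5 lists were called. Over members never at the floor the median moved from -0.37 to -0.29 for p53 (adjusted p = 0.0848), from -0.31 to -0.29 for miR-200 (0.0848), from -0.28 to -0.25 for miR-23/24/27 (0.0865), from -0.25 to -0.17 for hypoxia (0.0865) and from 0.22 to 0.05 for the GC-rich entries (0.0848).

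The 11 lists that were not called had adjusted p from 0.103 to 0.945. The adjusted p was 0.124 for miRNAs targeting NRF2 or KEAP1, the regulators of the oxidative stress response, 0.231 for intestinal epithelial miRNAs, 0.609 for miRNAs raised in colorectal tumours and 0.715 for blood miRNAs. It was 0.945 for the miR-17-92 cluster, 0.887 for let-7, 0.689 for miR-15/16, 0.304 for miR-29, 0.248 for miR-30, 0.945 for the miR-221 and miR-222 cluster and 0.103 for the entries overlapping tRNA or snRNA. In 3 of these the signs differed between measures: the mean log2 fold change was -0.02 for miR-17-92 and -0.01 for the miR-221 and miR-222 cluster where camera's direction was up, and 0.01 for let-7 where it was down.

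Over the 350 miRNAs tested, limma called 0, and 14 had an unadjusted p under 0.05, of which 0 were higher and 14 lower. Among the miRNAs above the floor on any array, the arrays of the groups did not overlap for 22, 0 higher and 22 lower. These are 9.91%, where chance gives 10% over both directions and 5% in 1 direction. The miRNAs are not independent of each other, and the spread of the chance share was not computed. miR-1271-5p, miR-142-5p and miR-4436b-5p, named after their values were seen, were detected on all control arrays and on no menadione array, but their control signal lay below the detection bound of the menadione arrays, so that 0 of these 3 gave a lower bound on the fold. With a block for the column of the slide limma called 75 miRNAs, but that estimate rests on menadione replicate 1, the only menadione array in the controls' column. Part of these calls had an adjusted p of 0 in limma, which arises where a fit leaves almost no residual spread. Examples were miR-1234-3p (0.29) and miR-1343-3p (0.79), whose log2 fold change in that fit was the same with either compound. Without control replicate 3 limma called 1 miRNA, miR-324-5p, and the p53, hypoxia and miR-23/24/27 lists lost their call (adjusted p = 0.214 each), and without menadione replicate 1 the GC-rich entries (adjusted p = 0.412) and miR-23/24/27 (0.0826) lost theirs.

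The comparison of plumbagin with vehicle asks the same question for the hydroxylated compound. No single miRNA passed the threshold in limma, and 7 lists were lower and 2 higher with camera at its preset correlation. Camera called 0 lists with an estimated correlation, where the smallest adjusted p was 0.256. miR-200b-3p, an epithelial miRNA of the miR-200 family, had a mean log2 scaled signal of 2.68 ± 0.02 (SD, n = 3) in controls and 2.09 ± 0.00 (n = 2) with plumbagin. Its log2 fold change of -0.58 (SE 0.10, a fold of 0.669) had a 95% interval from -0.83 to -0.33 and an adjusted p of 0.535. miR-15b-5p, of the family that represses cyclins and BCL2, averaged 1.99 ± 0.11 in controls and 1.5 ± 0.09 with plumbagin, a log2 fold change of -0.49 (SE 0.12, adjusted p = 0.678). Both plumbagin arrays lay below all 3 control arrays for each of them. The scaling rested on 366 probes in place of 285 without menadione replicate 1, and the log2 fold changes of plumbagin shifted by a median of 0.27 (range 0.13 to 0.27 over 140 miRNAs), which took their median from -0.15 to 0.12. miR-200b-3p was then at -0.31, outside the interval above, and miR-15b-5p at -0.22, and in the deposited series table they were at -0.26 and -0.18.

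Further miRNAs with a small unadjusted p were miR-10a-5p (-0.44, SE 0.11), miR-100-5p (-0.61, SE 0.17), let-7c-5p (-0.51, SE 0.14), miR-200b-5p (-0.54, SE 0.17) and miR-25-3p (-0.34, SE 0.11), each with an adjusted p of 0.678. The log2 fold change without menadione replicate 1 was -0.17 for miR-10a-5p, -0.35 for miR-100-5p, -0.24 for let-7c-5p, -0.27 for miR-200b-5p and -0.08 for miR-25-3p. miR-23b-3p had a log2 fold change of -0.43 (SE 0.15), or -0.16 without that array. Under 7 alternatives of scaling, background correction, signal column or source all 21 miRNAs named for plumbagin moved by over 1.5 times in at least 1 of them, as miR-25-3p did to -0.02 in the series table and miR-200b-5p to 0 under normexp. The common shift without scaling alone moves small fold changes by that much, so this count says little about single miRNAs. miR-375, which is abundant in endocrine cells of the gut and pancreas, and miR-10b-5p lay at the floor on both plumbagin arrays and averaged -2.70 ± 0.11 and -2.82 ± 0.17 in controls. All of these were lower on 2 of 2 plumbagin arrays than on any control array. On hg19 the probe of miR-200b-3p lies on chromosome 1 from 1102546 to 1102561 and that of miR-15b-5p on chromosome 3 from 160122398 to 160122416.

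All 9 members of the let-7 family, which represses RAS and other growth genes, were lower with plumbagin, with a mean log2 fold change of -0.43. In the deposited series table its mean lay above the mean of all miRNAs (-0.15 against -0.19) but below the median (0.11). Camera gave adjusted p = 3.33e-05, and adjusted p = 0.256 with an estimated correlation. Members let-7c-5p and let-7a-5p (-0.49, SE 0.19) had an adjusted p of 0.678 and 0.720. All 5 p53-responsive miRNAs were lower, with a mean of -0.54, adjusted p = 7.16e-05 and adjusted p = 0.256 with an estimated correlation, among them miR-107 (-0.41) and miR-192-5p (-0.56). In the miR-200 family 6 of 7 members were lower, with a mean of -0.42, adjusted p = 0.000677 and adjusted p = 0.256 with an estimated correlation. Fry's mixed test also called this family (adjusted p = 0.0219). Of 9 hypoxia-responsive miRNAs 8 were lower, with a mean of -0.36, adjusted p = 0.000530 and adjusted p = 0.340 with an estimated correlation, as with miR-24-3p (-0.50). All 5 members of the miR-23/24/27 clusters were lower, among them miR-27b-3p (-0.74, SE 0.26), with a mean of -0.44. In the deposited series table their mean lay above the mean of all miRNAs (-0.11 against -0.19) but below the median (0.11). Their adjusted p was 0.000370, and adjusted p = 0.256 with an estimated correlation. Under the 7 alternatives of processing each of these lists had its lowest mean without scaling, where the mean of all miRNAs was -0.28. The list mean ranged from -0.72 to -0.15 in the series table for let-7 (-0.21 with quantile normalization). The list mean ranged from -0.81 to -0.29 for p53, from -0.75 to -0.17 for miR-200, from -0.59 to -0.18 for hypoxia and from -0.70 to -0.11 for miR-23/24/27. For let-7 it was -0.20 without menadione replicate 1, of which 7 were then lower and 2 higher, and it was -0.29 for p53, -0.22 for miR-200, -0.12 for hypoxia and -0.17 for miR-23/24/27, where the mean of all miRNAs was 0.07. Of the members named here let-7a-5p was then at -0.22, miR-107 at -0.15, miR-192-5p at -0.29, miR-24-3p at -0.23 and miR-27b-3p at -0.48.

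In the miR-17-92 cluster and its paralogs, which promote proliferation, 12 of 14 members were lower and 0 higher, with a mean of -0.26. In the deposited series table their mean lay above the mean of all miRNAs (-0.11 against -0.19) but below the median (0.11). Camera gave adjusted p = 0.0128, and adjusted p = 0.441 with an estimated correlation, and miR-25-3p and miR-106b-5p (-0.54, SE 0.33) were examples. In the miR-15/16 family 3 of 4 members were lower, among them miR-16-5p (-0.44, SE 0.19), with a mean of -0.37. In the deposited series table its mean lay above the mean of all miRNAs (-0.15 against -0.19) but below the median (0.11). Its adjusted p was 0.00897, and adjusted p = 0.256 with an estimated correlation. Of 11 entries overlapping tRNA, snRNA or other abundant small RNA, 7 were higher and 4 lower, with a mean of 0.09 that turned to -0.17 without scaling between arrays. Their adjusted p was 0.00707, and adjusted p = 0.256 with an estimated correlation, with miR-1290 (0.38) and miR-3651 (0.25) as examples. Of 29 GC-rich entries 19 were higher and 1 lower, with a mean of 0.11 that turned to -0.05 without scaling, where the median of all miRNAs moved by -0.21. Their adjusted p was 7.16e-05, and adjusted p = 0.399 with an estimated correlation, with miR-1268a (0.58, SE 0.20) and miR-4516 (0.32) as examples. Under the 7 alternatives of processing the mean ranged from -0.49 to -0.09 for miR-17-92, from -0.70 to -0.15 for miR-15/16, from -0.17 to 0.42 for the tRNA-overlapping entries and from -0.05 to 0.45 for the GC-rich entries. In this order it was -0.03, -0.19, 0.36 and 0.38 without menadione replicate 1, with miR-25-3p at -0.08, miR-106b-5p at -0.27, miR-16-5p at -0.17, miR-1290 at 0.64, miR-3651 at 0.52 and miR-4516 at 0.58. Without control replicate 3 the mean was -0.12 for miR-17-92 and 0.19 for the tRNA-overlapping entries, with miR-106b-5p at -0.25 and miR-3651 at 0.08, and for the tRNA-overlapping entries it was 0.13 without control replicate 1 and -0.06 without control replicate 2. Members called over all miRNAs numbered 0 in every list, and adjusted over the list alone 2 were called, miR-200b-3p and miR-15b-5p.

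The 7 lists that were not called had adjusted p from 0.0615 for the miR-29 family to 0.871 for blood miRNAs. The adjusted p was 0.0729 for miRNAs targeting NRF2 or KEAP1, 0.123 for the miR-30 family, 0.222 for intestinal epithelial miRNAs, 0.569 for miRNAs raised in colorectal tumours and 0.866 for the miR-221 and miR-222 cluster. The fold changes of plumbagin went with the GC content of the probes. Over the 140 miRNAs above the floor on all arrays, which are not independent replicates, Spearman's rho was 0.738, against 0.337 for menadione. With probe length rho was -0.724 for plumbagin and -0.298 for menadione. Whether the trend follows GC content or probe length was not tested. Per array, the GC slope was -0.06 ± 0.07 log2 per 10% (SD, n = 3) in controls, 0.00 ± 0.15 (n = 3) with menadione and 0.08 ± 0.03 (n = 2) with plumbagin, with exact permutation p = 0.2 for plumbagin against control, 0.7 for menadione against control and 0.5 for plumbagin against menadione. The median log2 fold change with plumbagin was 0.05 for the 75 miRNAs with the higher GC content and -0.40 for the 65 with the lower. The median GC content of the tested members was 42.1% in the let-7 family, 47.1% in the miR-200 family, 47.4% among p53-responsive miRNAs and 83.3% among the GC-rich entries. With GC content regressed out, chosen after the data were seen, the p53, miR-200 and tRNA-overlapping lists passed the threshold and the other 6 called lists did not. Over members never at the floor the median moved from -0.54 to -0.41 for p53-responsive miRNAs, from -0.58 to -0.44 for miR-200 and from 0.11 to -0.03 for the tRNA-overlapping entries, whose sign thus turned. It moved from -0.43 to -0.36 for miR-23/24/27 (adjusted p = 0.0650), from -0.38 to -0.29 for hypoxia-responsive miRNAs (0.129), from -0.48 to -0.22 for let-7 (0.593), from -0.33 to -0.19 for miR-17-92 (0.593) and from -0.49 to -0.31 for miR-15/16 (0.203). That of the GC-rich entries turned from 0.18 to -0.12 (0.948).

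Limma called 0 of 350 miRNAs, and 22 had an unadjusted p under 0.05, of which 3 were higher and 19 lower. Among the miRNAs above the floor on any array, the groups did not overlap for 83, 16 higher and 67 lower (37.4%, where chance gives 20%). These miRNAs are not independent of each other, and the spread of the chance share was not computed. Of miRNAs detected on all control arrays, 18 were detected on no plumbagin array, and miR-6808-3p, named after its values were seen, showed the opposite. Only 2 of these 19 gave a lower bound on the fold above 1, the highest at least 1.20-fold. The others lay below the detection bound of the undetected arrays, except miR-615-3p, which had no mean log2 signal. The signals behind these bounds lay below the floor of -3.22 used in the fits. They averaged -4.11 for miR-1247-3p in controls and -4.37 for miR-6808-3p with plumbagin. Fitted with the controls alone, limma called 1 miRNA, miR-200b-3p (adjusted p = 0.0316, over a range from 0.000121 to 1 across the alternatives). With array weights it called 14, and with a block for slide column it called 83. The block also gave the lowest value of that range. Its estimate rests on menadione replicate 1 as the only link between the columns of these groups. Without menadione replicate 1 limma called 3 miRNAs, and the miR-17-92 list, with a mean of -0.26 on all arrays, lost its call without control replicate 3 (adjusted p = 0.340, mean -0.12), menadione replicate 1 (0.235, mean -0.03) or plumbagin replicate 2 (0.0923, mean -0.22). The miR-15/16 list lost its call without control replicate 3 (0.0636, mean -0.28 beside -0.37) and the tRNA-overlapping entries without control replicate 2 (0.913, mean -0.06 beside 0.09).

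**Figure D2:**
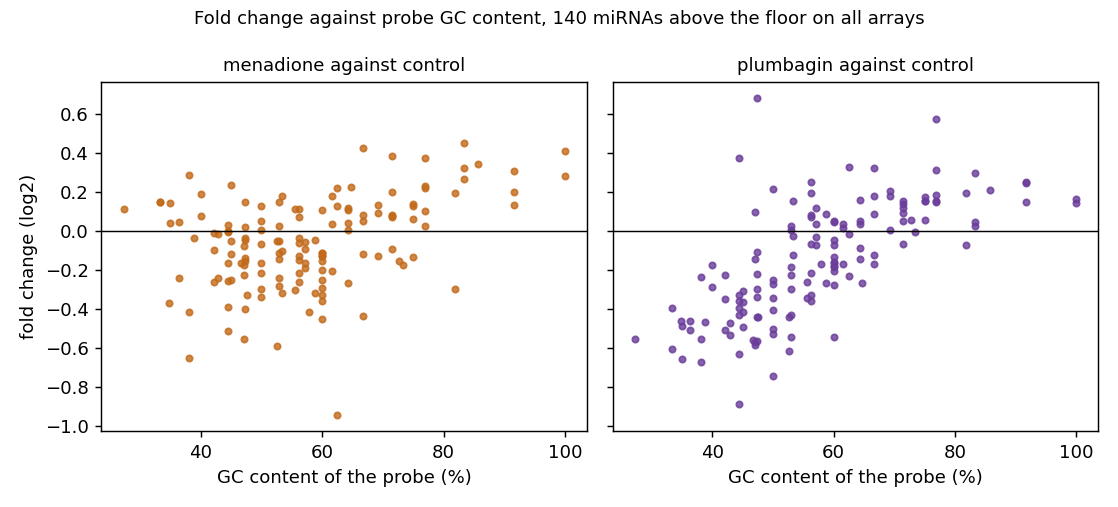
Log2 fold change against the GC content of the probe in percent, for menadione and for plumbagin against control, with 1 point per miRNA for the 140 miRNAs above the floor on all 8 arrays. Points rose with GC content more steeply with plumbagin (0.14 log2 per 10%) than with menadione (0.06), and per array the slope of these groups differed with an exact permutation p of 0.5.

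Plumbagin and menadione share the naphthoquinone core and were given at the same dose and time, so their direct comparison asks whether the added hydroxyl group goes with a different response. No single miRNA passed the threshold in limma, and 3 lists were lower with plumbagin by camera at its preset correlation: let-7, miR-17-92 and miR-15/16. For these the smallest adjusted p with an estimated correlation was 0.712. let-7g-5p averaged 1.23 ± 0.23 (SD, n = 3) with menadione and 0.39 ± 0.09 (n = 2) with plumbagin. Its log2 difference of -0.85 (SE 0.29, a fold of 0.557) had a 95% interval from -1.57 to -0.12 and an adjusted p of 1. miR-15b-5p averaged 1.94 ± 0.17 with menadione, a difference of -0.44 (SE 0.12) with an interval from -0.73 to -0.15, or -0.27 without menadione replicate 1 and -0.20 with the percentile over all probes. The probe of let-7g-5p lies on chromosome 3 of hg19 from 52302300 to 52302319.

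All 9 let-7 members were lower with plumbagin, by a mean of -0.43, with adjusted p = 1.49e-05 and adjusted p = 0.712 with an estimated correlation. The mean was -0.24 with the percentile over all probes, -0.22 with quantile normalization and -0.25 without scaling. Fold changes of this comparison also went with probe GC content (Spearman's rho 0.458 over 140 miRNAs) and with probe length (rho -0.472). With GC content regressed out the let-7 median moved from -0.40 to -0.28 (adjusted p = 0.116). That of miR-17-92 moved from -0.35 to -0.29 (0.116) and that of miR-15/16 from -0.40 to -0.32 (0.284), so that 0 of the 3 lists were called. let-7a-5p differed by -0.53 (SE 0.19, interval from -1.0 to -0.06), or -0.17 with quantile normalization. In the miR-17-92 cluster and its paralogs 11 of 14 were lower and 1 higher, by a mean of -0.24, or 0.01 in the deposited series table where the mean of all miRNAs was 0.08, with adjusted p = 0.0441 and adjusted p = 0.968 with an estimated correlation. This mean was -0.13 without menadione replicate 1, where that of all miRNAs was 0.10. Its member miR-25-3p differed by -0.46 (SE 0.11, interval from -0.74 to -0.17), or -0.28 without menadione replicate 1 and -0.18 with quantile normalization. miR-17-3p had a higher signal with plumbagin, but it lay at the floor on 2 menadione arrays, so that the difference depends on the floor and went from 0 under normexp to 2.07 in the series table. In the miR-15/16 family 3 of 4 members were lower, by a mean of -0.28, with adjusted p = 0.0441 and adjusted p = 0.712 with an estimated correlation, and miR-16-5p differed by -0.40 (interval from -0.86 to 0.06), or -0.03 with quantile normalization. The miR-15/16 mean was -0.17 with the percentile over all probes. Outside these lists miR-200b-3p differed by -0.36 (SE 0.10, interval from -0.61 to -0.11), which was -0.20 without menadione replicate 1 and turned to 0.02 under quantile normalization. miR-196a-5p, which lies within HOX clusters, differed by -0.54 (SE 0.18, interval from -1.0 to -0.08), or -0.30 with the percentile over all probes, and miR-183-5p lay at the floor on both plumbagin arrays and averaged -2.78 ± 0.16 with menadione. The named miRNAs had an adjusted p of 1, and a p that misses the threshold does not show that the compounds act alike. Members called over all miRNAs numbered 0, and miR-15b-5p alone was called when adjusted over the list alone.

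The 13 other lists had adjusted p from 0.180, for p53-responsive miRNAs, to 0.906. It was 0.315 for miR-23/24/27, 0.480 for miRNAs raised in colorectal tumours, 0.631 for entries overlapping tRNA or snRNA, 0.755 for hypoxia-responsive miRNAs, 0.756 for miR-29 and 0.906 for the miR-200, miR-30, NRF2 or KEAP1, intestinal, blood, miR-221 with miR-222 and GC-rich lists. Camera's direction was up for some of these with a mean below 0, such as the GC-rich entries (-0.06) and blood miRNAs (-0.03).

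Limma called 0 of 350 miRNAs and 9 had an unadjusted p under 0.05, of which 1 was higher and 8 lower. The groups did not overlap for 46 of the miRNAs above the floor on any array, 19 higher and 27 lower (20.7%, where chance gives 20%). Within the slide column that holds both plumbagin arrays and 2 menadione arrays, limma called 26 miRNAs, 3 higher and 23 lower with plumbagin. Named after these values were seen, they included let-7g-5p (-0.98, adjusted p = 0.0353), let-7f-5p (-0.95), miR-26b-5p (-1.03) and miR-21-5p (-0.53), an abundant oncogenic miRNA. With array weights, whose estimation stopped before it converged and which gave menadione replicate 1 a weight of 0.0432, limma called 65 miRNAs, and it called 1 with that array left out. The let-7 list kept its call with each array left out (adjusted p from 2.93e-06 to 0.0179) by camera at its preset correlation, against adjusted p = 0.712 with an estimated correlation on all arrays. The miR-17-92 and miR-15/16 lists lost theirs without menadione replicate 2 (0.701 and 0.228), menadione replicate 3 (0.364 and 0.355) or plumbagin replicate 2 (0.274 and 0.0874), and miR-15/16 also without control replicate 3 (0.0722). In these fits the miR-17-92 mean was -0.16, -0.20 and -0.21 beside -0.24 on all arrays, and the miR-15/16 mean was -0.23, -0.23, -0.24 and -0.28 beside -0.28.

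**Figure D3:**
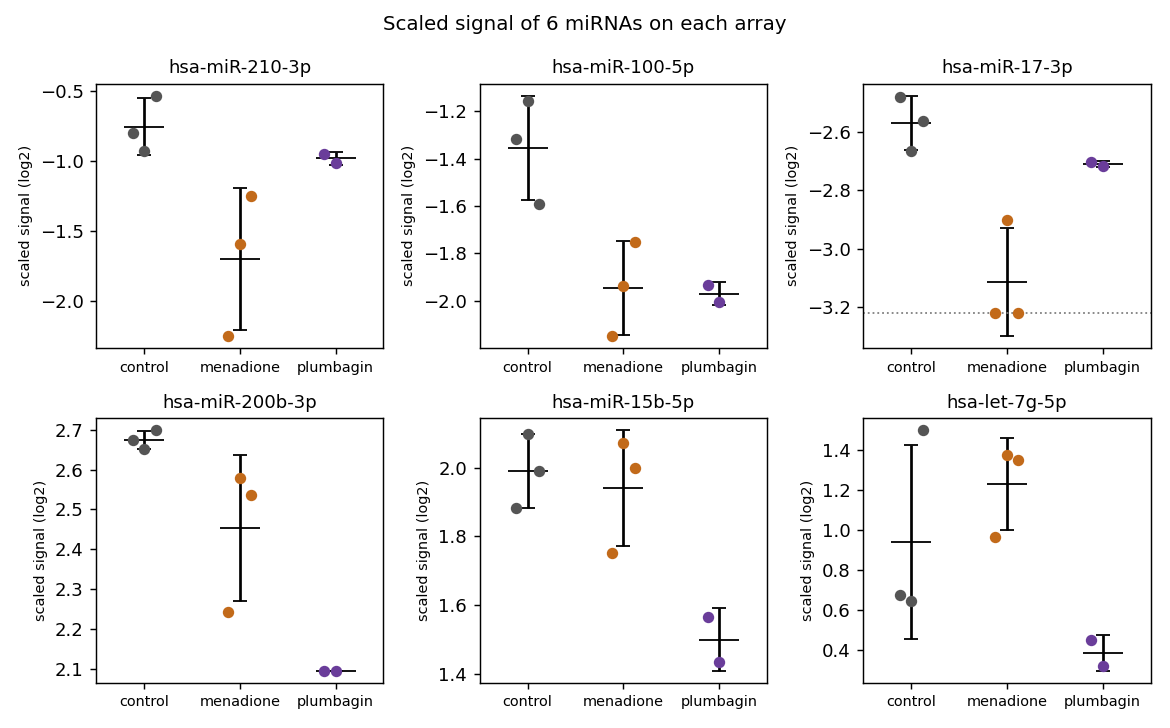
Scaled log2 signal of 6 miRNAs on each array by group, with points for arrays, a dash for the group mean, bars for the SD and a dotted line at the floor where an array reached it. miR-210-3p lay lower on all 3 menadione arrays than on any control array, and miR-200b-3p and let-7g-5p lay lower on both plumbagin arrays than on any menadione array.

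**Figure D4:**
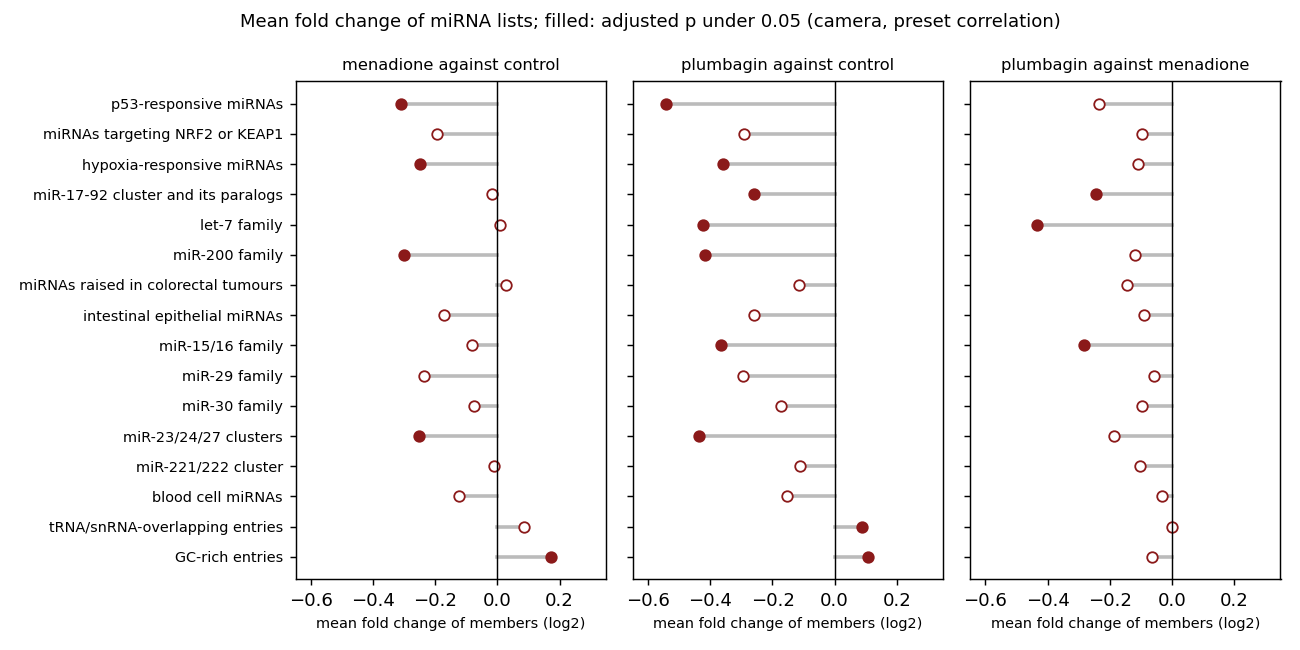
Mean log2 fold change of the tested members of each list in the 3 comparisons, filled where camera at its preset correlation gave an adjusted p under 0.05. The let-7 family had a mean of 0.01 with menadione and -0.43 with plumbagin against control, and the GC-rich entries (0.17 and 0.11) turned to -0.20 and -0.05 without scaling, where the mean of all miRNAs was -0.33 and -0.28, while miR-17-92 between the compounds (-0.24) was 0.01 in the deposited series table, where the mean of all miRNAs was 0.08.

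The responses to the compounds were compared across miRNAs, which are not independent replicates, to ask how much they share. Pearson's r between their log2 fold changes was 0.479 and Spearman's rho 0.504 over 350 miRNAs. Simulated unchanged groups that share their controls gave a median r of 0.592 with 95% of values from -0.80 to 0.98 when the correlation between miRNAs was kept, and 0.450 when miRNAs were independent. The covariance was 0.0176, against simulated medians of 0.00871 and 0.0136. Of the miRNAs above the floor on any array 62.6% had the same sign, against 69.8% and 64.9%. miR-100-5p (-0.59 and -0.61) and miR-10a-5p (-0.33 and -0.44) had negative log2 fold changes with either compound (-0.35 and -0.17 with plumbagin without menadione replicate 1), whereas let-7g-5p averaged 0.94 ± 0.49 in controls, between its mean of 1.23 with menadione and 0.39 with plumbagin. The miRNAs called with both compounds numbered 0, since limma called 0 with either, beside 14 and 22 at an unadjusted p under 0.05. Without menadione replicate 1, r was 0.00511, and with array weights it was 0.113.

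Among markers of other cell types, 0 of 6 miRNAs of fibroblast and smooth muscle and 0 of 9 of endothelium, muscle, liver and neuron passed the detection filter. Of 17 miRNAs lowered in colorectal tumours 2 passed it, miR-378a-3p and miR-9-3p, which are too few for a list test. Of the 9 blood miRNAs 3 were tested, and 1 of them lay above the floor on all arrays.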

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

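The tests of GC content and of menadione replicate 1 below were chosen only after the results were seen, and those of the splits of the arrays and of simulated unchanged data were written before.

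The difference between plumbagin and menadione was itself tested, and 3 lists fixed before the data were examined differed by camera at its preset correlation. All 9 let-7 members were lower with plumbagin (adjusted p = 1.49e-05), as were 11 of 14 members of the miR-17-92 list (adjusted p = 0.0441), with a mean of -0.24, or 0.01 against 0.08 for all miRNAs in the deposited series table, and 3 of 4 of the miR-15/16 family (adjusted p = 0.0441). With an estimated correlation the adjusted p was 0.712, 0.968 and 0.712. In 70% of simulated unchanged data sets that kept the correlation between miRNAs, at least 3 lists were called, so that correlation among the miRNAs of an array may account for this number of lists. The dim menadione replicate 1 was not the source of the calls, since all 3 lists were called the same way without it (adjusted p = 0.000235, 0.00522 and 0.00772), among 5 in all. Of the let-7 members 7 were then lower and 2 higher, with a mean of -0.36 where that of all miRNAs was 0.10. A difference between the compounds stays open.

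The lists called against control are the second pattern. Simulated unchanged data gave at least as many called lists as menadione did (5) in 52% of draws and as plumbagin did (9) in 21%, so correlation among the miRNAs of an array may account for the number called in either comparison. The 10 splits of the 3 control and 3 menadione arrays are too few for a share under 0.05. As many lists as in the real comparison (5) were called in 6 of them, with at most 10 in another split. All 10 splits called at least the real 0 miRNAs by construction (14 at an unadjusted p under 0.05 in limma), which tests nothing. The highest count of miRNAs in another split was 22. That split set control replicates 1 and 2 and menadione replicate 1 against the other 3 arrays. It was picked from the 10 splits as the highest, and a structure of the samples other than treatment was not tested. A response to the compounds stays open as the biological explanation.

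The third pattern is that the fold changes of plumbagin followed probe GC content (Spearman's rho 0.738 over 140 miRNAs), although the GC slope per array gave an exact permutation p of 0.2 against control. They also followed probe length (rho -0.724), which the tests below cannot tell from GC content. A GC trend also ran within groups: over the 7 pairs of arrays of 1 group the median size of rho was 0.414, with a highest size of 0.747, so a trend between arrays unrelated to treatment may account for at least part of it. Over the 8 arrays the GC slope went with the log2 75th percentile of the signal, with Spearman's rho -0.881 (exact permutation p = 0.00724) and Pearson's r -0.82 (exact permutation p = 0.00126) for 1 relation tested, and r = -0.73 without menadione replicate 1 and control replicate 3, so the amount of labelled RNA on an array is a candidate explanation. Both measures come from miRNA signals of the same arrays, so a change in those miRNAs could move both. No separate measure of RNA input was set against the slope. The columns of the slide hold 4 arrays each, too few for the relation within them. With GC content regressed out 3 lists were called in plumbagin against control, 2 without control replicate 3 and 1 without menadione replicate 1, and 0 lists were called in all of these fits, which cannot tell GC content as the whole cause from a response in some lists. The median of 8 let-7 members moved from -0.48 ± 0.15 (SD over members) to -0.22 ± 0.11, and that of 5 miR-200 members from -0.58 ± 0.28 to -0.44 ± 0.24 (adjusted p = 0.0310), and no biological explanation of a GC trend was tested.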

How the results depend on the processing

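The fits without miRNAs at the floor on any array, with the negative-control floor and with GC content regressed out were chosen only after the data were seen. With 0 miRNAs called in every comparison (14, 22 and 9 at an unadjusted p under 0.05 in limma), 28 of 32 alternatives for menadione against control, 25 of 32 for plumbagin against control and 25 of 33 for plumbagin against menadione also called 0. The fit with no filter could not be fitted.

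For menadione against control, plumbagin against control and plumbagin against menadione, in that order, a block for the column of the slide called 75, 83 and 1 miRNAs, the negative-control floor 1, 3 and 1, and GC content regressed out without control replicate 3 called 14, 5 and 13. GC content regressed out without menadione replicate 1 called 3 and 2 in the comparisons of plumbagin with control and with menadione, and array weights, whose estimation stopped before it converged, called 14 and 65. The fit of only the compared groups called 1 miRNA for plumbagin against control. For plumbagin against menadione the summed intensity called 1 miRNA and the fit within slide column 2 called 26. With each array left out the counts ranged from 0 to 1 (1 without control replicate 3), 0 to 3 (3 without menadione replicate 1) and 0 to 1 (1 without menadione replicate 1). The slide-column estimates against control rest on menadione replicate 1, the only treated array in the controls' column. For the other alternatives the cause was not tested.

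The lists called numbered 5, 9 and 3 in the same order. They became 2, 2 and 1 with the percentile over all probes, 0, 1 and 1 without scaling, 0, 3 and 0 with GC content regressed out, 1, 2 and 1 with this and without control replicate 3, and 0, 1 and 0 with this and without menadione replicate 1. An estimated correlation gave 0, 0 and 0, fry's directional test 0, 0 and 0, and its mixed test 0, 1 and 0. For menadione 3 lists were called among miRNAs never at the floor. For plumbagin against menadione 1 list was called with quantile normalization, 7 with the slide-column block and 7 within slide column 2. With each array left out they ranged from 2 to 7 for menadione (2 without control replicate 3), from 7 to 10 for plumbagin, and from 1 to 5 between the compounds (5 without menadione replicate 1, and 1 without menadione replicate 2, menadione replicate 3 or plumbagin replicate 2). The cause was not tested.

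A block for replicate number called 0 miRNAs in each comparison (8, 7 and 7 at an unadjusted p under 0.05) and 5, 9 and 1 lists, with r = 0.470 between the responses. The labels do not say whether the numbers pair the samples. The correlation of deviations between arrays with the same number ranged from -0.62 to 0.37. No such values for arrays with different numbers were set beside it, so it cannot show whether the samples are paired. The correlation between the responses, 0.479, was 0.113 with array weights, 0.908 with the slide-column block and 0.174 with GC content regressed out without menadione replicate 1, and ranged from 0.00511 without menadione replicate 1 to 0.640 with each array left out. The cause was not tested.

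Of 863 values of named miRNAs under the alternatives that kept all arrays, 791 kept their direction and their side of the threshold, 17 were 0 and so had no direction, 49 passed the threshold and 6 reversed. With an array left out these were 483, 0, 12 and 3 of 498. Without scaling, which moved the median of all miRNAs by -0.30 with menadione and -0.21 with plumbagin, miR-7704 (-0.0428) and miR-3196 (-0.17) with menadione and miR-3651 (-0.00747) with plumbagin reversed but stayed above that median. The percentile over all probes moved the median by -0.11 with menadione, and the series table moved it by 0.11 with plumbagin. miR-140-3p with menadione reversed under normexp (0.0166), miR-1290 with plumbagin under the slide-column block (-0.20), and miR-200b-3p between the compounds under quantile normalization (0.0232). With GC content regressed out without menadione replicate 1, miR-107 (0.0159) and let-7a-5p (0.0695) with plumbagin and miR-183-5p between the compounds (0.0493) reversed. The cause was not tested. The chosen floor limits the fits, as 128 of 350 tested miRNAs lay at it on all arrays. In simulated data with 60 of 350 miRNAs changed, 19%, 65.5% and 90.8% of log2 changes of 0.5, 1 and 2 were recovered for menadione. For plumbagin these were 16.3%, 52.5% and 90.3%. Fewer changes, changes in miRNAs at the floor and noise correlated between miRNAs were not tested, so real fits may differ.

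Relative to the mean of all tested miRNAs, the means of the lists called with menadione ranged over 7 alternatives of scaling, background correction, signal column or source from -0.46 to 0.08 (p53), -0.36 to -0.17 (hypoxia), -0.50 to -0.08 (miR-200), -0.42 to 0.18 (miR-23/24/27) and 0.08 to 0.43 (GC-rich). With plumbagin they ranged from -0.53 to -0.10 (p53), -0.35 to -0.18 (hypoxia), -0.21 to 0.08 (miR-17-92), -0.44 to 0.03 (let-7), -0.47 to -0.10 (miR-200), -0.42 to 0.04 (miR-15/16), -0.42 to 0.08 (miR-23/24/27), 0.06 to 0.61 (tRNA-overlapping) and 0.08 to 0.64 (GC-rich), and between the compounds from -0.18 to -0.07 (miR-17-92), -0.39 to -0.25 (let-7) and -0.36 to -0.20 (miR-15/16). Every value above 0 of a list that was otherwise lower came from the deposited series table. There the median of all miRNAs was 0.004 with menadione and 0.11 with plumbagin, and each of these list means lay below it.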

Other observations

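The values here were chosen only after the data were seen, and the fits with GC content regressed out were added then. miR-22-3p had the highest log2 fold change with plumbagin against control of the miRNAs tested, 0.68 (a fold of 1.61, adjusted p = 0.678). With GC content regressed out its log2 fold change was 0.83 (SE 0.17, adjusted p = 0.0814), and it was 0.96 (adjusted p = 0.00994) without control replicate 3 and 1.08 (adjusted p = 0.00617) without menadione replicate 1. Against menadione it was 0.61 (adjusted p = 0.187) with GC content regressed out and 0.81 (adjusted p = 0.0487) with this and without menadione replicate 1.

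Among miRNAs never at the floor, miR-210-3p had a log2 fold change of -0.94 with menadione (adjusted p = 0.0524) and -0.97 (adjusted p = 0.211) with GC content regressed out. The prior degrees of freedom were 20.7 in the first of these fits. In the limma fit of all 350 miRNAs they were 0.677, and the adjusted p of miR-210-3p was 0.919. The log2 difference of miR-210-3p between plumbagin and menadione was 0.72 (adjusted p = 0.349 in the fit of miRNAs never at the floor). Its range of adjusted p over the alternatives for menadione against control was 0.00699 to 1. The lowest came with the block for slide column, an estimate that rests on menadione replicate 1.

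Between arrays of 1 group the SD of the log2 differences was 0.16 for menadione replicates 2 and 3 and 0.17 for the plumbagin replicates, against 0.29 to 0.56 for pairs of controls and 0.60 to 0.62 for menadione replicate 1 against the other menadione arrays. Between arrays of different groups it went from 0.25 (control replicate 3 with menadione replicate 2) to 0.72 (control replicate 3 with menadione replicate 1). Control replicate 3 thus lay closer to menadione replicates 2 (0.25) and 3 (0.29) than to control replicates 1 (0.37) and 2 (0.56). Of 37 control probes on the arrays 32 lay above background, and for 0 of them all arrays of a compound lay above all control arrays in unscaled signal. For 17 of the 32 both plumbagin arrays lay below all control arrays (chance gives 10% in 1 direction), and for 4 all menadione arrays did (chance gives 5%). Apart from the bright-corner probe, all of these had names starting with hur. Probes with names starting with dmr or mr were not among them, and the types of probe were not compared by a test. These probes are not independent of each other.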
